A study of Astyanax mexicanus with 6 samples.

How the data were processed

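Eyes were dissected at about 54 hours post-fertilization from embryos of the cave morph and the surface morph of Astyanax mexicanus, the Mexican tetra, and RNA and DNA were taken from the eyes with a single kit, per the labels' protocols. Poly(A) RNA was sequenced in 2 libraries per morph, and whole-genome bisulfite sequencing (WGBS), in which unmethylated cytosines are read as thymine, in 1 library per morph. The labels do not say whether the 2 RNA libraries of a morph came from separate pools of embryos, so p-values measure the spread between these libraries, which may be technical. The submitters' processing notes name Trimmomatic, STAR, Subread, featureCounts, Bismark and DESeq2 without versions. The genome build, the width of the upstream region, the cytosine context and any removal of duplicate reads are not given in the sources used here.

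The RNA table holds the authors' raw counts per gene, as whole numbers with a different total in each library. Totals were 132739496 and 117742250 in the cave libraries and 146907747 and 154476181 in the surface libraries. Among counts of 1 to 30, between 74.4% and 86.6% were even in the 4 libraries, as would happen if both mates of most read pairs were counted; no other source of the even counts was tested. The methylation table holds the authors' counts of methylated and unmethylated calls per gene, in a gene body and in an upstream region per the file headers. It holds 43378558 and 42555064 calls upstream for the cave and the surface library, and 469015502 and 448796711 in gene bodies. The median number of calls per upstream region was 1004 and 924. Methylation percentages were computed here from those counts. Each methylated and unmethylated value of the cave library is even, so its calls were also halved as an alternative chosen after seeing the data.

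A further deposited table holds the authors' own comparison of the morphs. Per the file headers it gives a mean signal over the libraries, a log2 fold change with its standard error, a score (the fold change over its error), and a p-value with its adjusted form. Its values are named as the authors' where printed. By the names of the count columns its sign runs opposite to cave minus surface. Gene symbols were taken from the deposited tables, with the suffix that marks several copies removed. Genes that share a symbol or have a near copy can share reads. Positions are given as the files give them, on scaffolds.

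Groups came from the sample labels alone. Because photoreceptor genes differed between the RNA groups in a direction that the closing observations weigh as a possible exchange of labels, RNA libraries are called labelled cave or labelled surface. The RNA counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, its default filter on low counts, quasi-likelihood test, 2 against 2 libraries), with Benjamini-Hochberg adjustment and a threshold of 0.05, which left 22850 genes. The standard error printed is the size of the log2 fold change divided by the square root of its F statistic. CPM scales each count by the total of its library. A gene with 0 counts in both libraries of a group has its fold computed against a floor of 6 counts over the group, which is 3 read pairs if each pair gave 2 counts, and intervals and floors cover counting error only. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. With an estimated correlation camera rests on the few degrees of freedom that 2 against 2 libraries leave, so even a large shift can miss the threshold. Fry asks whether the genes of a list move one way on balance and compares the list with no other genes.

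Each region with at least 20 calls in each WGBS library was compared by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment, and called where the adjusted p was below 0.05 and the difference at least 10 percentage points. With 1 library per morph this compares those 2 libraries, not the morphs, and calls on 1 read are not independent, so these p-values and the 95% exact (Clopper-Pearson) intervals are too narrow. Overlaps of calls were tested by Fisher's exact test among genes tested for both, and the correlation across genes by permuting genes 100000 times, where genes are not independent replicates. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

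The genes named were fixed by rule before the data were examined, as were 23 gene lists, the tests and most alternatives. The rule took 10 genes higher and 10 lower with the largest fold change among those with a symbol that is not a clone or locus name, past the threshold at an average log2 CPM of 1 or more with both cave libraries on the same side of both surface libraries. It also took the DNA methyltransferase and tet genes, a set of eye genes, up to 4 genes per list, the upstream regions with the largest changes at 50 or more calls in each library, and the genes called in both data types with the largest expression change. It gave 84 genes, 53 of them past the threshold for expression. Genes of the rule whose symbols were not matched are not analysed here. The result of 1 gene named by the rule is not reported here. Alternatives were other scaling factors, no filter and a stricter filter, DESeq2 1.42.0, limma-voom, a replicate block, each RNA library left out in turn, other call minimums and differences, and a fold threshold of 1.5.

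The scripts were tested on simulated data. With counts drawn for 22574 genes in the cave against surface design, the expression test called 0%, 42%, 76% and 86% of genes changed by a log2 fold of 1, 2, 3 and 5, with 15 false calls. These 15 stood beside 0, 21, 38 and 43 true calls, a larger share than the threshold of 0.05 allows. Only genes with a mean count of 100 or more were changed. The methylation test on 23680 simulated upstream regions called 83% of changes of 15 points and 100% of changes of 25 points. Its changed regions all had intermediate methylation and its calls were drawn as independent, so both simulations show favourable cases.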

Results

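Gene expression and DNA methylation were measured in eyes from the cave morph and the surface morph of Astyanax mexicanus at about 54 hours post-fertilization. The cave morph forms eyes in the embryo that later degenerate, and the series title places the study on an epigenetic route to that loss. There were 2 RNA libraries and 1 WGBS library per morph. The RNA libraries labelled surface resembled each other more (Spearman correlation of 0.989 across genes) than those labelled cave (0.944), and cave replicate 1 correlated with surface replicate 1 at 0.943. The median absolute log2 difference between replicates was 0.48 in the cave pair and 0.28 in the surface pair.

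The first comparison asks which genes differ in expression between the eyes of the morphs. Genes of photoreceptors were far more abundant in the libraries labelled cave. The rod opsin gene rho had 17664 and 26989 counts in the libraries labelled cave against 0 and 7 in those labelled surface, a log2 fold change of 12.98 (SE 0.91; edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.00454). The long-wavelength cone opsin gene opn1lw1 (ENSAMXG00000006368, scaffold KB871987.1, 251107 to 253611) stood at 997 ± 216 CPM against 4.42 ± 1.94 CPM (SD, n = 2), a log2 fold change of 7.92 (SE 0.45, edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.00279). The outer segment disc gene rom1a had 2 counts in the surface group, which gives a ratio of 8479 with a counting interval of 1521 to 334952 if each read pair gave 2 counts. Of 22850 genes tested, 633 were higher and 93 lower in the libraries labelled cave, of which 482 and 36 carried a symbol.

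Among genes past the threshold with a symbol and an average log2 CPM of 1 or more, the others that rose most were the lens gene crybgx (log2 11.39), the pteridine synthesis gene gch2 (10.01), arl13a (8.90), the purine phosphorylase gene pnp4a (8.69), tulp1a (8.41), the cone transducin subunit gene gnb3b (8.22) and the short-wavelength opsin gene opn1sw2 (7.90). Their adjusted p-values from edgeR with Benjamini-Hochberg adjustment lay between 0.00149 and 0.00592. The gene crybgx overlaps its neighbour lctla in position, so reads may be shared between them. Among genes past the threshold under the same limits, those that fell most were pebp1 (log2 -7.83), the uncoupling protein gene ucp1 (-6.41), tph2, which encodes a serotonin synthesis enzyme (-5.13), kynu of tryptophan breakdown (-4.92), il22ra2 (-4.27), PDE9A (-3.89), pou3f2a (-3.09), sh2d4bb (-3.04), ipmka (-2.89) and nkx2.4b (-2.71). Their adjusted p-values from the same edgeR test with Benjamini-Hochberg adjustment lay between 0.00841 and 0.0448.

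These counts depended on the libraries used. With 1 library left out, a group holds 1 library and the spread comes from the other pair alone. Calls and p-values of such fits, here and below, ignore the spread between the 2 libraries of that group. Without cave replicate 1 there were 2989 genes higher and 4203 lower, and without cave replicate 2 there were 2611 and 1958, with all 633 and 93 genes shared in both cases. Without surface replicate 1 edgeR called 0 genes, with 1895 at an unadjusted p under 0.05, and without surface replicate 2 it called 0, with 1605 at that level. DESeq2, run on all 4 libraries only, called 1593 higher and 756 lower.

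**Figure D1:**
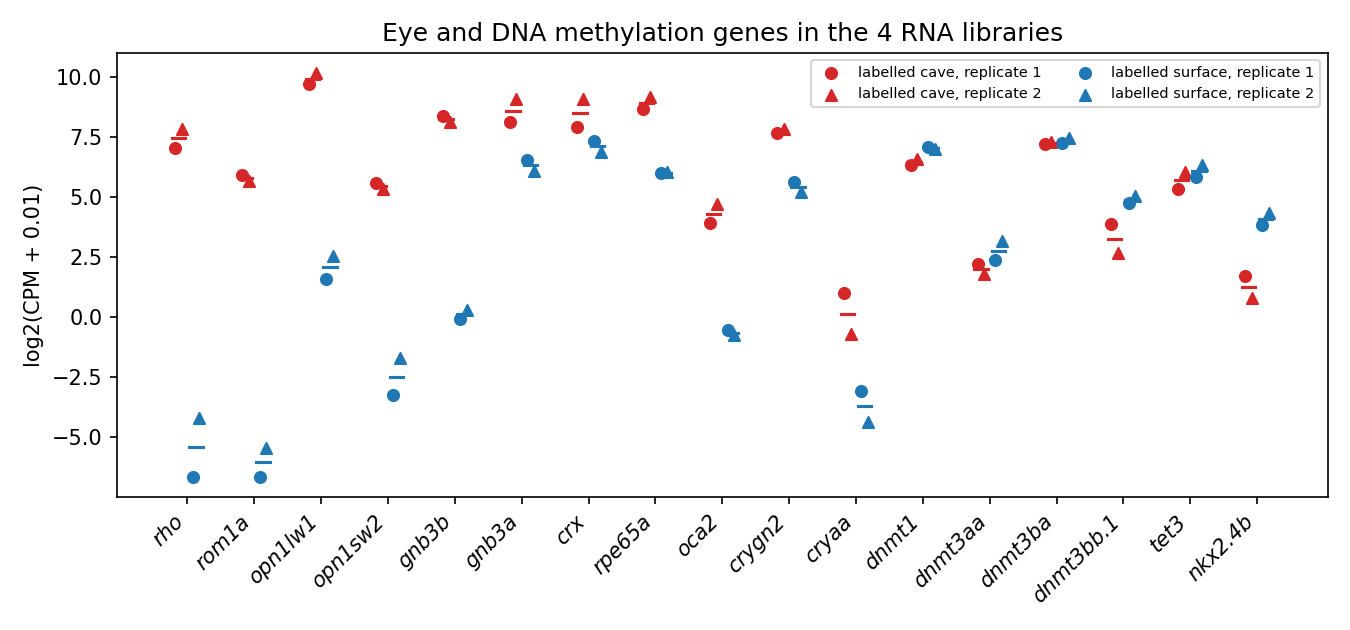
Abundance of selected eye genes, DNA methylation genes and nkx2.4b in each RNA library, as log2 of CPM plus 0.01, with circles for replicate 1, triangles for replicate 2 and bars for the mean of each pair. The gene opn1lw1 averages 997 CPM in the libraries labelled cave and 4.42 CPM in those labelled surface, while dnmt3ba averages 153 and 165 CPM.

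Genes of phototransduction rose together. In the rod list 16 of 21 tested members were higher and 0 lower (17 adjusted over the list alone), with a median log2 fold change of 4.85, the same with rhol at its bound. The gene rhol had 0 counts in both libraries labelled surface and was at least 167-fold higher in the cave group, and rom1b rose by log2 6.71. In the cone list 22 of 27 members were higher and 0 lower (24 adjusted over the list alone), with a median of 4.89, the same with guca1d at its bound. The gene guca1d was at least 48.3-fold higher and gnb3a, a cone transducin subunit gene (ENSAMXG00000019064, KB882139.1, 2564433 to 2584439), rose by log2 2.42 (SE 0.42; edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.048). Camera gave adjusted p = 8.69e-18 for the rod list and 3.00e-24 for the cone list (Benjamini-Hochberg over 22 lists), against adjusted p = 0.214 for both with an estimated correlation.

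Genes of bipolar cells and of the pigment epithelium were also higher as lists. The bipolar cell list had 8 of 20 members higher (12 adjusted over the list alone), with grm6b at log2 5.55, cabp2a at 4.52, neto1 at 4.25 and cabp5a at 3.97, a median of 1.51 and a camera adjusted p of 6.79e-09 (Benjamini-Hochberg; adjusted p = 0.607 with an estimated correlation). Without cave replicate 1 edgeR called 17 of them higher. The list of retinal pigment epithelium and pigment cells had 11 of 26 members higher (21 adjusted over the list alone, with 1 lower), among them lrata (6.07), the melanosome gene oca2 (5.10), stra6 (2.96) and the retinoid isomerase gene rpe65a, at 491 ± 115 against 65.1 ± 1.36 CPM (SD, n = 2). Its median was 1.62 and its camera adjusted p 9.26e-11 (Benjamini-Hochberg; adjusted p = 0.607 with an estimated correlation). DESeq2 called 19 higher, and edgeR called 23 higher and 2 lower without cave replicate 1 and 17 and 1 without cave replicate 2. Among retinal transcription factors 1 of 31 was higher, nrl, a rod regulator, at log2 3.06 (1 adjusted over the list alone), while DESeq2 called 7 higher. EdgeR called 22 higher and 2 lower without cave replicate 1, and 7 and 4 without cave replicate 2. The list median was 0.71 and camera gave an adjusted p of 0.0279 (Benjamini-Hochberg), with adjusted p = 0.765 with an estimated correlation, 0.965 without cave replicate 2 and 0.167 without surface replicate 2. The photoreceptor regulator gene crx (ENSAMXG00000001577, KB882311.1, 289812 to 296772) stood at 394 ± 217 against 142 ± 31.8 CPM (SD, n = 2), a log2 fold change of 1.55 that was not past the threshold (edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.162; DESeq2, adjusted p = 0.0444). The eye field genes were not past it in edgeR either, with log2 values of 1.76 and 0.71 for the copies named rx1 and 1.15 for rx3, while DESeq2 with Benjamini-Hochberg adjustment called the first rx1 copy (adjusted p = 0.00569). All 4 values depended on the cave library used. Without cave replicate 1 the log2 values were 2.04 for crx, 2.19 and 1.06 for the rx1 copies and 1.63 for rx3. Without cave replicate 2 they were 0.71 for crx, 1.05 and 0.18 for the rx1 copies and 0.36 for rx3.

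Lens genes were higher as lists. Of 14 crystallin genes tested 2 rose, crybgx and crygn2 (218 ± 15.2 against 43.2 ± 8.68 CPM; SD, n = 2), and 10 did so adjusted over the list alone; the median was 2.06. DESeq2 called 8 higher, and edgeR called 10 higher and 1 lower without cave replicate 1 and 9 higher without cave replicate 2. Camera gave adjusted p = 2.94e-05 (Benjamini-Hochberg; adjusted p = 0.510 with an estimated correlation). The alpha crystallin gene cryaa had 265 and 71 counts against 16 and 6 and was not past the threshold (log2 4.16, SE 1.01; edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.110; DESeq2, adjusted p = 0.00122; edgeR without cave replicate 1 and 2, adjusted p = 0.0164 and 8.06e-06). Other lens genes had 4 of 26 higher (8 higher and 2 lower adjusted over the list alone), BFSP1 (5.38), lim2.3 (3.93), bfsp2 (3.52) and lctla (3.02), with a median of 0.31. DESeq2 called 8 higher and 3 lower, and edgeR without either cave replicate 9 and 4. Their camera adjusted p was 0.0279 (Benjamini-Hochberg; adjusted p = 0.595 with an estimated correlation, 0.187 without cave replicate 2 and 0.149 without surface replicate 2).

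Lists that were lower in the libraries labelled cave held few single calls by edgeR on all 4 libraries. The forebrain and hypothalamus list had 1 of 21 lower, nkx2.4b (2 adjusted over the list alone), a median of -1.91 and a camera adjusted p of 1.15e-07 (Benjamini-Hochberg; adjusted p = 0.735 with an estimated correlation). DESeq2 called 7 lower, and edgeR called 20 lower without cave replicate 1 and 14 without cave replicate 2. Its median over the surface mean was -1.14 in cave replicate 1 and -3.94 in cave replicate 2. Of 29 genes of epidermis and cornea edgeR called 0, with 0 adjusted over the list alone and agr2 at log2 -3.08 (DESeq2 with Benjamini-Hochberg adjustment, adjusted p = 0.236). The size for agr2 depended on the cave library, at -6.31 without cave replicate 1 and -2.25 without cave replicate 2. The list median was -0.51 and its camera adjusted p 0.0094 (Benjamini-Hochberg; adjusted p = 0.765 with an estimated correlation, 0.253 without cave replicate 2 and 0.0602 without surface replicate 1). At an unadjusted p under 0.05 it held 1 gene and DESeq2 called 0, while edgeR called 25 lower without cave replicate 1 and 2 higher and 1 lower without cave replicate 2. That list stood at 0.29 over the surface mean in cave replicate 1 and at -2.58 in cave replicate 2. Of 31 macrophage and neutrophil genes edgeR called 0 (0 adjusted over the list alone), with LYZ at log2 -4.33. DESeq2 with Benjamini-Hochberg adjustment called LYZ (adjusted p = 3.53e-05). The size for LYZ was -5.64 without cave replicate 1 and -3.75 without cave replicate 2. Of that list 6 were at an unadjusted p under 0.05, DESeq2 called 4 lower, and edgeR called 13 lower without cave replicate 1 and 2 higher and 6 lower without cave replicate 2. The median was -0.52 and the camera adjusted p 0.0103 (Benjamini-Hochberg; adjusted p = 0.765 with an estimated correlation and 0.462 without surface replicate 1). Of 42 cell cycle genes edgeR called 0 (0 adjusted over the list alone), with aurkb at -0.94. DESeq2 with Benjamini-Hochberg adjustment called aurkb (adjusted p = 0.0484). The size for aurkb was -0.78 without cave replicate 1 and -1.20 without cave replicate 2. In the list 7 were at an unadjusted p under 0.05, DESeq2 called 1 lower, and edgeR called 2 higher and 2 lower without cave replicate 1 and 1 higher and 9 lower without cave replicate 2. The median was -0.26 and the camera adjusted p 0.0289 (Benjamini-Hochberg; adjusted p = 0.765 with an estimated correlation, 0.716 without cave replicate 1 and 0.609 without surface replicate 1).

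**Figure D2:**
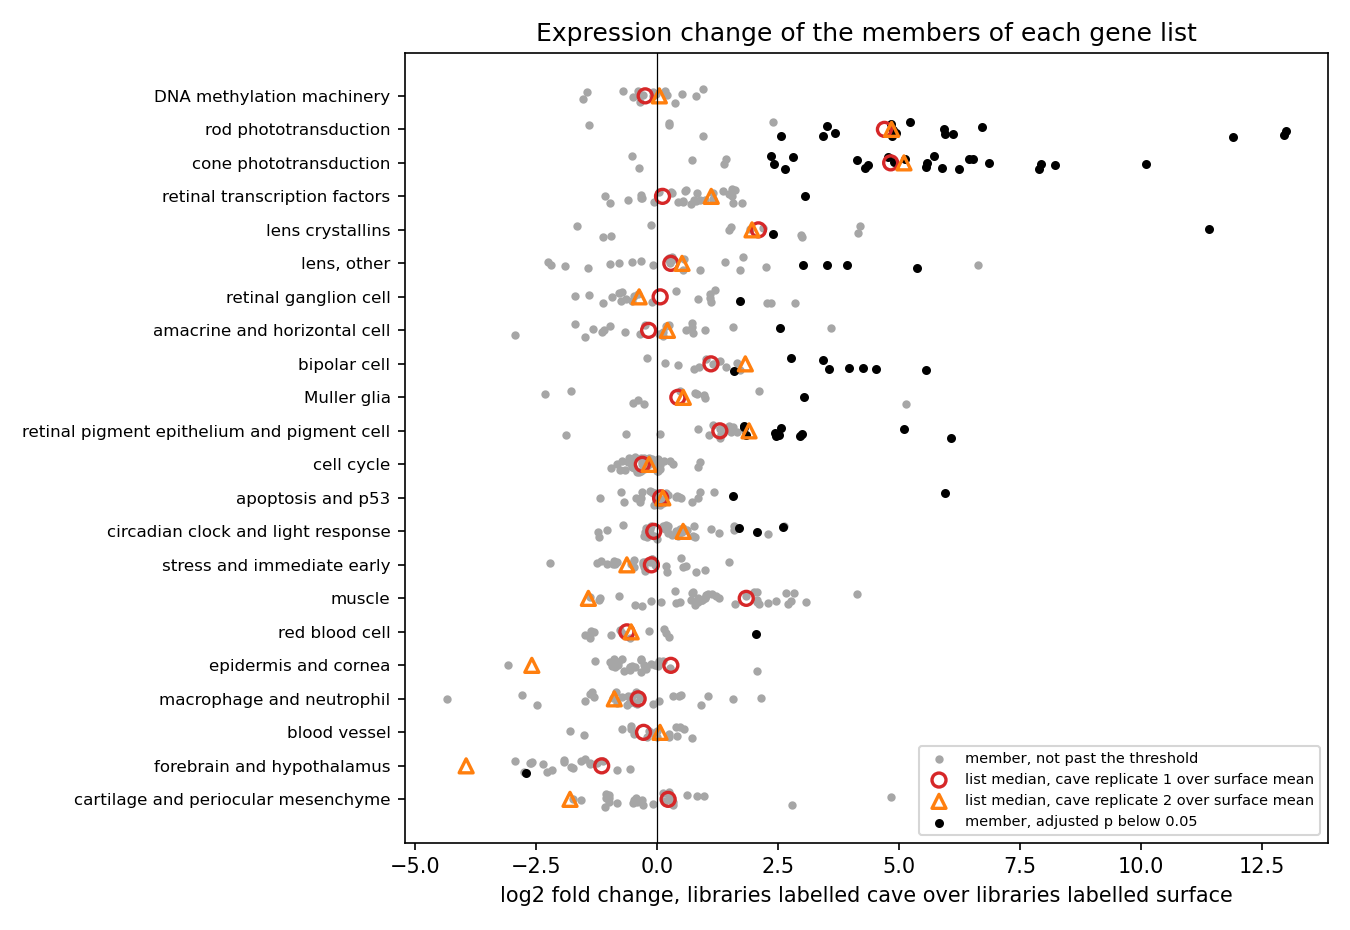
Log2 fold change of each tested member of 22 gene lists, libraries labelled cave over libraries labelled surface, with black points past the threshold and grey points not. Red circles and orange triangles give the list median in cave replicate 1 and cave replicate 2 over the surface mean; for muscle these lie at 1.85 and -1.41.

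The study's title concerns an epigenetic mechanism, so the enzymes that write and remove DNA methylation were compared next. EdgeR on all 4 libraries called 0 of the list of 16, with 0 adjusted over the list alone, 3 at an unadjusted p under 0.05 and a median of -0.08 (camera adjusted p = 0.501, Benjamini-Hochberg). DESeq2 called 2 lower, and edgeR called 3 higher and 2 lower without cave replicate 1 and 4 lower without cave replicate 2. The de novo methyltransferase gene dnmt3bb.1 (ENSAMXG00000019567, KB882128.1, 3002772 to 3062345) had the smallest p, at 10.5 ± 5.85 CPM against 30.1 ± 4.70 CPM (SD, n = 2) and a log2 fold change of -1.45 (SE 0.42; edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.157). DESeq2 with Benjamini-Hochberg adjustment put it past the threshold (adjusted p = 0.021). Its log2 fold change was -2.13 without cave replicate 1 and -1.07 without cave replicate 2. The maintenance enzyme gene dnmt1 was at -0.50, dnmt3aa at -0.69, dnmt3ba at -0.02 and tet3, which encodes an enzyme that oxidizes methylcytosine, at -0.28. Without cave replicate 2 dnmt1 stood at -0.73 and tet3 at -0.79, while without cave replicate 1 they stood at -0.36 and 0.052. The sulfur amino acid genes cbsa and cbsb were at 0.38 and -0.19 and the heat shock factor gene hsf2 at -0.10, none past the threshold.

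The authors' deposited table lists 743 genes with a positive and 1577 with a negative fold change at an adjusted p under 0.05. Its fold change had a Spearman correlation of -0.970 across genes with the cave minus surface fold change computed here by DESeq2. In the authors' deposited table opn1lw1 has a log2 fold change of -7.26, rho -2.19 and dnmt3bb.1 1.35. For rho, with 0 and 7 counts in the libraries labelled surface, that size is far below the 12.98 from edgeR here. The cause was not tested, so sizes of such low-count genes should not be compared. All 633 genes higher in the libraries labelled cave by edgeR are negative there among its calls, and 92 of the 93 lower genes are positive. By the names of the count columns the sign of the authors' deposited table is therefore surface minus cave. Its headers name no direction. If it runs cave minus surface instead, the count columns are exchanged, and its sign alone cannot tell these apart.

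The next comparison asks whether DNA methylation differs between the eyes of the morphs. Over all upstream regions 52.9% of calls were methylated in the cave library and 53.3% in the surface library, a difference of -0.381 points that became 1.05 points without the 100 regions with the most calls. Over gene bodies the levels were 79.0% and 78.1%, a difference of 0.978 points. The exact Clopper-Pearson intervals of these levels are at most a few hundredths of a point wide and cover counting error only. Of 23680 upstream regions 2855 were more and 2054 less methylated in the cave library, and of 25016 gene bodies 787 were more and 498 less methylated.

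Among named upstream regions the largest rises were at grap2a (94.0% against 14.8%), nipa2 (88.4% against 10.6%), ppwd1 (79.0% against 2.16%), pcdh2ac (89.2% against 13.2%), th (86.8% against 15.3%) and VGLL3 (75.7% against 5.54%). The largest falls were at adipor1a (9.76% against 93.5%), MAP1B (8.16% against 89.8%), uts2a (6.38% against 77.2%) and vps53 (4.97% against 69.6%). Between 77 and 1981 calls per library stood behind these values. None of these 10 genes was past the threshold for expression in edgeR. DESeq2 with Benjamini-Hochberg adjustment called th lower (log2 -1.69 in edgeR, DESeq2 adjusted p = 0.025). The log2 fold change of VGLL3 was -1.92 without cave replicate 1 and -0.32 without cave replicate 2. The upstream region of opn1lw1 was methylated at 93.0% of 1146 calls in the cave library and 56.2% of 1300 calls in the surface library. That of gnb3a stood at 96.7% against 80.9%, that of crx at 40.6% against 20.2% and that of cbsb at 84.4% against 71.7%, all called higher in the cave library. Other eye genes were called lower in it: rom1b at 30.5% against 76.1%, lim2.3 at 61.0% against 82.4% and the second rx1 copy (ENSAMXG00000021639) at 27.5% against 39.7%. The regions of dnmt1 (8.43% against 5.35%) and rho (93.4% against 95.7%) were not called.

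No gene list held more methylation calls than other genes after adjustment. The smallest p was that of epidermis and cornea, with 7 of 27 upstream regions more methylated (two-sided Fisher's exact test, p = 0.037, Benjamini-Hochberg adjusted p = 0.703). In the cone list 6 of 25 regions were more methylated and 4 less, and in the rod list 2 of 22 each way.

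The last comparison asks whether genes with more upstream methylation in the cave library had less RNA in the libraries labelled cave. Among 21465 genes tested for both, 8 were more methylated and lower in expression, where 9.61 were expected (odds ratio 0.813, interval 0.338 to 1.69; Fisher's exact test, p = 0.730, Benjamini-Hochberg adjusted p = 0.827 over 8 overlaps). The 4 of these with a usable symbol were PDE9A, SLC25A24 (log2 -2.28), abcc13 (-2.10) and prdx4 (-1.26). Without cave replicate 2 the odds ratio was 0.743 (Fisher's exact test, p = 2.39e-04). The opposite overlap, added after seeing the data, held 110 genes more methylated and higher in expression where 72.6 were expected (odds ratio 1.66, interval 1.33 to 2.05; Fisher's exact test, p = 7.84e-06, Benjamini-Hochberg adjusted p = 6.28e-05). Among these were opn1lw1, AIFM2 (log2 7.40) and irgq2 (6.96). In gene bodies, in an overlap also added after seeing the data, 9 genes were less methylated and lower in expression where 1.64 were expected (odds ratio 6.08; Fisher's exact test, p = 3.96e-05, Benjamini-Hochberg adjusted p = 1.58e-04). This did not hold without cave replicate 1 (odds ratio 0.986, Fisher's exact test, p = 0.949) or without cave replicate 2 (odds ratio 0.778, Fisher's exact test, p = 0.247).

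**Figure D3:**
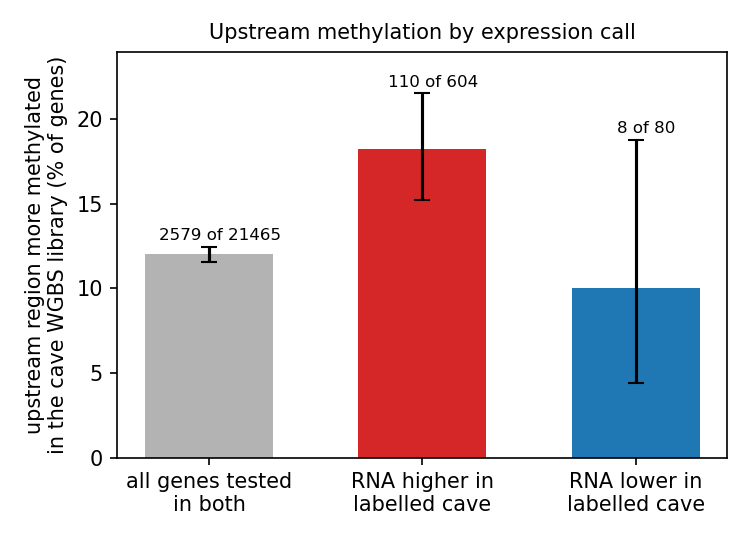
Percentage of genes whose upstream region was called more methylated in the cave WGBS library, for all genes tested for both measures and for genes higher or lower in RNA labelled cave, with exact 95% binomial intervals as bars. The share is 18.2% of 604 higher genes, 2579 of all 21465 genes and 10% of 80 lower genes, where the interval of the lower genes spans 4.42% to 18.8%.

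Across those genes the change in upstream methylation and the change in expression had a Spearman correlation of 0.0283 (permutation p = 4.00e-05) and a Pearson correlation of 0.0375 (permutation p = 1e-05, the smallest that 100000 permutations can give). For gene bodies, added after seeing the data, the values were 0.0311 and 0.0325. All 4 relations had Benjamini-Hochberg adjusted p-values of at most 4.00e-05. Genes are not independent replicates. The directions of these overlaps and correlations rest on the labels. If the RNA labels alone were exchanged, the upstream overlap with lower expression would have the odds ratio of 1.66 and that with higher expression 0.813. The gene body overlap with lower expression would have 1.27 (Fisher's exact test, p = 0.358). If the WGBS labels alone were exchanged, these 3 odds ratios would be 0.692, 0.958 and 2.06 (Fisher's exact test, p = 0.553, 0.827 and 0.107). In either case the Spearman correlation would be -0.0283.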

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

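Halving of cave calls, leaving out the 100 regions with the most calls, all overlaps except that of more upstream methylation with lower expression, the gene body correlation and the exchange of RNA labels against WGBS labels were chosen after seeing the data. RLE and upper quartile scaling, no filter, a stricter filter and limma-voom kept the expression counts within 1.5 times of 633 and 93; upper quartile scaling moved the median of all genes from 0.02 to -0.08. DESeq2 called 1593 and 756 (67.8% higher against 87.2%), and an unadjusted p with 1.5-fold called 2585 and 1421. A replicate block called 318 and 35, of which 314 and 34 were shared; same-numbered libraries share only a number (correlation of deviations -0.0719). Leaving out 1 library gave 0 to 2989 higher and 0 to 4203 lower, where the lone library is assumed to vary like the other pair. Of the 53 called genes that were named, 31 kept the call with the block, all kept it without either cave replicate, and 0 without either surface replicate; none reversed. Of the 31 named genes not called, DESeq2 called 11, edgeR without cave replicate 1 called 15 and without cave replicate 2 called 13.

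Camera with an estimated correlation called 0 lists higher and 0 lower, against 7 and 4, and fry 3 and 0. Those called by fry were the rod, cone and crystallin lists (fry with Benjamini-Hochberg adjustment, adjusted p = 0.00483, 0.00367 and 0.00483). For the list of other lens genes this loss need not come from correlation within the list. Its estimated correlation was -0.022, under the preset 0.01, and it still went from a camera adjusted p of 0.0279 to 0.595. The rod, cone and crystallin lists had 0.044, 0.029 and 0.058. Bipolar cell, pigment epithelium and retinal transcription factor lists had 0.39, 0.46 and 0.63. The lists called lower had 0.42 for macrophages and neutrophils, 0.61 for cell cycle, 0.92 for forebrain and 0.99 for epidermis. For lists far above the preset, p-values at the preset may be too small. The block changed calls of lists for cell cycle (adjusted p = 0.0693, lost), circadian genes (0.0484, gained) and cartilage (0.0296, gained). Leaving out 1 library gave 1 to 6 lists lower. The upstream methylation difference reversed to 1.05 points and the body difference moved to 0.910 without the 100 regions with the most calls. With no minimum difference 8283 upstream regions were more and 5617 less methylated, and 11992 and 5529 gene bodies; at 25 points the counts were 512, 415, 125 and 65. The overlap with lower expression reversed to an odds ratio of 1.17 at 25 points (Fisher's exact test, p = 0.690) and ranged from 0.743 to 0.909 with either cave library left out. With the RNA labels exchanged, the overlap with lower expression has an odds ratio of 1.66 and that with higher expression 0.813. With the WGBS labels exchanged instead, they have 0.692 and 0.958. In both cases the correlation is -0.0283. The gene body overlap of less methylation with lower expression has 1.27 with the RNA labels exchanged and 2.06 with the WGBS labels exchanged. It has 5.72 at 25 points (Fisher's exact test, p = 0.165) and 1.26 with an unadjusted p and 1.5-fold (Fisher's exact test, p = 0.211). With either cave library left out it has 0.778 to 0.986. Without either surface library no gene is called, so no overlap was computed.

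Uncalled genes changed sign when 1 library was left out, with ranges of -0.60 to 0.30 for MAP1B, -0.61 to 0.083 for cbsb, -0.10 to 0.32 for cox2, -0.17 to 0.039 for dnmt3ba, -0.47 to 0.14 for hsf2, -0.39 to 0.088 for ppwd1 and -0.79 to 0.052 for tet3. Fewer samples limit these fits; for the other changes the cause was not tested.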

Other observations

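The other lists held few calls by edgeR on all 4 libraries. In the circadian and light response list 3 of 39 members rose in the libraries labelled cave, cry1bb at log2 2.60, cry4 at 2.06 and cry1ba at 1.69 (5 higher and 1 lower adjusted over the list alone). The list itself was not past the threshold (median 0.31, camera adjusted p = 0.0506, Benjamini-Hochberg). In the apoptosis list CASP6 (5.95) and casp3a (1.58) rose among 31 members (2 adjusted over the list alone, median 0.03, camera adjusted p = 0.501, Benjamini-Hochberg). The size for CASP6 was 4.63 without cave replicate 1 and 6.55 without cave replicate 2. The Muller glia list had rlbp1a higher (3.04) among 13 members (2 higher and 1 lower adjusted over the list alone). Its median was 0.79 and its camera adjusted p 0.202 (Benjamini-Hochberg). The ganglion cell list had rbpms2a higher (1.72) among 22 (4 higher and 1 lower adjusted over the list alone), with a median of -0.25 and a camera test pointing up (adjusted p = 0.970). The amacrine and horizontal cell list had calb2b higher (2.55) among 23 (3 adjusted over the list alone), with a median of 0.12 and a camera test pointing down (adjusted p = 0.970).

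The red blood cell list had rhag higher (2.05) among 13 members (1 adjusted over the list alone; median -0.72, camera adjusted p = 0.153, Benjamini-Hochberg). EdgeR called no member in the lists of muscle, cartilage and periocular mesenchyme, blood vessel and stress, nor adjusted over each list alone. In these lists 7, 3, 2 and 8 members had an unadjusted p under 0.05. They held 41, 28, 18 and 30 genes, with medians of 1.00, -0.31, -0.04 and -0.26. Camera gave the lists adjusted p-values of 0.383, 0.0506, 0.518 and 0.0909 (Benjamini-Hochberg). The gene printed for each was nexn at 1.23, col1a1a at 4.84, stab2 at -1.51 and junbb at -0.90. DESeq2 called 6 muscle genes higher and 1 lower, 1 cartilage gene higher, 2 blood vessel genes lower, and 1 stress gene higher and 4 lower. DESeq2 with Benjamini-Hochberg adjustment called the gene printed for each of these lists, nexn (adjusted p = 0.00348), col1a1a (2.29e-05), stab2 (0.0023) and junbb (0.0135). The muscle list reversed with the cave library used: its median was -1.42 without cave replicate 1 (camera adjusted p = 9.45e-04) and 1.76 without cave replicate 2 (4.18e-11). Leaving out a cave library also moved the medians of several of these lists. The circadian median was 0.54 without cave replicate 1 and -0.17 without cave replicate 2. The cartilage median was -1.80 without cave replicate 1 and 0.14 without cave replicate 2. The stress median was -0.64 without cave replicate 1 and -0.22 without cave replicate 2, and the ganglion cell median -0.38 and -0.10. The mitochondrial list had 2 members, too few for a test, with cox2 at 0.14.

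Of the tests that follow, those of muscle transcripts, of depletion by 2-fold and 8-fold, of depleted against random genes, of the calls among depleted genes and of genes selected on cave replicate 1 were chosen after the results were seen.

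Photoreceptor genes were higher in the RNA libraries labelled cave, opposite to what eye loss in the cave morph would lead one to look for. A candidate explanation is that RNA and WGBS labels were exchanged against each other. Genes short of DNA calls in the surface WGBS library would then have little RNA in the libraries labelled cave. The planned test at 4-fold depletion gave a difference of medians of -2.39, on the side of the exchange. With 72 against 9 genes its permutation p was 0.104, so this test alone did not decide between the exchange and correct labels. Versions added later gave -0.969 at 2-fold (permutation p = 4.90e-04) and -2.53 at 8-fold (22 against 2 genes, permutation p = 0.396); the 72 genes lay below random genes (permutation p = 1e-05, the smallest possible) and held 8 lower calls (odds ratio 33.4, Fisher's exact test, p = 5.36e-10) and 3 higher calls (odds ratio 1.53, p = 0.454). Of the lower calls, ENSAMXG00000025407 and ENSAMXG00000028856 had 1325550 and 1431889 gene body calls in the surface WGBS library, where the median was 8176. Neither was short of DNA calls there. Of the higher calls, si:ch211-193k19.2 had 263 and 386 counts in RNA labelled cave and 0 and 0 in RNA labelled surface. That is the side of correct labels. The lower calls ENSAMXG00000027304 and ENSAMXG00000024829 had 0 counts in both libraries labelled cave, the side of the exchange. Against an exchange of both label sets, 110 genes were depleted in the library labelled surface and 20 in that labelled cave (binomial p = 2.99e-16). This reading assumes a reference from a cave fish. For a smaller retinal share in the libraries labelled surface, inner retinal genes had a median of 0.67 (bootstrap interval 0.08 to 1.04) where phototransduction genes had 4.86. This cannot decide the retinal share, since brain tissue in the libraries labelled surface could hold that median down. The forebrain list was higher in them (cave minus surface median -1.91). The inner retinal lists also split, with medians of 1.51 for bipolar cells, -0.25 for ganglion cells and 0.12 for amacrine and horizontal cells. Less mature eyes in the libraries labelled surface stay open, since the cell cycle median of -0.26 lay below random lists (-0.07 to 0.23), although that list's call was lost with an estimated correlation, and a difference between the morphs themselves was not tested.

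Cave replicate 1 correlated with surface replicate 1 (0.943) nearly as it did with cave replicate 2 (0.944). Other tissue in that library may account for it: the median over 6 lists of other cell types was log2 2.44 over cave replicate 2, with muscle at 3.14, epidermis and cornea at 3.17, cartilage at 2.55 and forebrain at 2.32, but red blood cell at -0.08 and blood vessel at -0.28. The surface libraries also stood above cave replicate 2. Cave replicate 2 over the surface mean was -1.41 for muscle, -2.58 for epidermis and cornea, -1.79 for cartilage and -3.94 for forebrain. It was -0.53 for red blood cell and 0.07 for blood vessel. Forebrain was below the surface mean in cave replicate 1 too (-1.14). Falls of forebrain genes such as nkx2.4b therefore cannot be told apart from a difference in the tissue taken. RNA from surface eyes as the source of the muscle transcripts is argued against by a muscle median of 1.85 over the surface mean (bootstrap interval 1.57 to 2.46). Mixing of surface RNA otherwise cannot be told apart from selection, since genes over 20-fold above the surface libraries in cave replicate 2 had a median of -0.36 (interval -0.47 to -0.26) in replicate 1 over replicate 2, while those selected on replicate 1 had -0.06 (-0.14 to 0.05). No biological explanation was tested.

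Each of the 101084 values of the cave WGBS library was even, against 48543 odd values (48.0%) in the surface library. What made them even was not tested. With its calls halved, 2741 upstream regions were more and 1978 less methylated.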
